A study of Caenorhabditis elegans with 4 samples.

How the data were processed

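The samples came from Caenorhabditis elegans hermaphrodites of strain OP49, which carries an integrated transgene encoding the zinc-finger protein LIN-13 fused to EGFP and a FLAG tag, together with an unc-119 rescue marker. LIN-13 is a product of the synthetic multivulva class B genes, a group of chromatin and transcription regulators that includes the worm retinoblastoma protein. Per the labels, animals were collected at the first larval stage (L1) after growth at 20 °C on plates seeded with bacteria, and the stage entry also carries the text 26dC, whose meaning the labels do not give. Per the labels' protocols, chromatin was fixed with 2% formaldehyde, sheared by sonication and precipitated with goat antibodies against GFP, and 10% of the lysate was kept as input DNA. The series holds 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in their titles. Groups were taken from the titles and source names. The free-text descriptions are the other way round: the antibody is listed on the samples titled Input, and the words input DNA stand alone on the samples titled ChIP. The replicate peak lists belong to the samples titled ChIP. The labels do not say whether the replicates came from separate cultures.

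The data analysed were 3 peak lists, 1 for each ChIP replicate and 1 called combined. Per the file headers and source column, the authors called the peaks with PeakSeq, a program that scores ChIP reads against a control, on WormBase WS180 coordinates. Each deposited row gives a chromosome, a start, an end and the authors' q-value (a p-value corrected for multiple testing). No read count, fold enrichment, summit or gene name stands in the lists, so the sequencing depth behind each list is unknown. The aligner, the PeakSeq version, the q limit, the use of the input libraries and the way the replicates were combined are not given in the sources used here. The q-value is the authors' own value for each peak. It was used to rank peaks within a list, mostly as −log10 q, and it depends on depth and on the width of a peak as well as on enrichment.

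Overlap was computed from the deposited starts and ends, and peaks that shared at least 1 bp counted as shared. Chance overlap came from 10000 random placements of the peaks of one list within their own chromosomes with widths kept, and the one-sided p was the share of placements with at least as many overlaps. The chromosome length used was the last peak end on that chromosome in any of the 3 lists. Placement was uniform, with no allowance for open chromatin or mappability, so it sets a floor and not a model of accessible sites. Shares carry exact (Clopper-Pearson) 95% intervals and densities carry exact Poisson 95% intervals. Both cover counting error over peaks only, and neighbouring peaks are not independent. Correlations of −log10 q were tested with 100000 permutations and differences of medians with 100000 (combined peaks in both against neither) or 10000 (all others), all two-sided. Where a combined peak met more than 1 peak of a replicate, the strongest was used. Chromosome shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 6 chromosomes. Peaks and regions are not replicates of the experiment, so these p-values describe the lists and not the spread between animals. The analysis used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

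The overlap code was tested on simulated lists made for the comparison of the replicate lists, which hold 243 and 367 peaks. Of 100 pairs of randomly scattered lists, 4 gave p under 0.05. All 100 pairs with 60 planted shared peaks did, and on average 60 of the 60 planted peaks were recovered. Planted peaks were copied from the simulated replicate 2 list and moved by 50 bp, less than the narrowest width of 208 bp. Their recovery was therefore fixed in advance and checks the code only. The null lists were scattered uniformly, as the test assumes, so they do not cover clustered peaks. The permutation of medians was tested on simulated groups of equal size drawn from normal distributions. There, 26 of 400 null sets and 50 of 50 shifted sets gave p under 0.05. The groups compared below differ in size and hold −log10 q values of called peaks only, so this checks the code and not that setting.

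The regions named in the text followed a rule fixed before the data were examined: the 15 combined peaks with the lowest q among those that overlapped a peak of both replicates, and the strongest peak of each replicate list that overlapped no peak of the other. Other named regions were chosen after their values were seen, and the text says so. The alternatives tried were a 50% reciprocal overlap, midpoints within 200 bp, the stronger 50% of each list, a q limit 10 times lower, merging of peaks within 200 bp, log2-transformed values, removal of the 10 strongest regions, and leaving out each replicate list. No genome or annotation of WS180 was used here, and the gene table at hand was built on another assembly (WBcel235). Distances to gene starts, tests of gene lists, and the lin-13 and unc-119 loci were therefore not analysed here, and regions are given by WS180 coordinates, 1-based. The share of peaks on the X chromosome was not tested against chromosome length for the same reason. No signal from the input libraries was analysed here.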

Results

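LIN-13 binding was mapped by chromatin immunoprecipitation and sequencing in first-stage larvae of Caenorhabditis elegans that express an EGFP-tagged LIN-13. The ChIP was made as 2 replicates with 2 input libraries, and the question addressed was where in the genome LIN-13 lies in vivo. The replicate 1 list held 243 peaks covering 182 kb and the replicate 2 list held 367 peaks covering 293 kb, a mean of 305 ± 87.7 peaks (SD, n = 2). The combined list held 911 peaks covering 763 kb, 3.75 times as many peaks as replicate 1 and 2.48 times as many as replicate 2. Median peak widths were 492 bp in replicate 1, 508 bp in replicate 2 and 552 bp in the combined list. The highest q listed was 3e-05 in replicate 1, 4.59e-05 in replicate 2 and 8.64e-05 in the combined list. The q limit of each list is not given in the sources used here. The read depth of the libraries is unknown, and part of the difference in list length can come from it.

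The strongest combined peak lay on the X chromosome, at X 16929246 to 16932023, with q = 2.61e-84. It was the strongest peak of replicate 2 (q = 3.53e-57) and stood at q = 9.64e-30 in replicate 1. The second was on the same chromosome, at X 1503457 to 1505228, with q = 1.32e-71. This region was the strongest of replicate 1 (q = 6.32e-31) and reached q = 1.04e-43 in replicate 2. A 629 bp peak at III 10758850 to 10759478 followed, with q = 4.88e-51 in the combined list, 4.39e-27 in replicate 1 and 5.22e-37 in replicate 2. Of the 15 strongest combined peaks that both replicate lists also held, 4 were on X, 3 on chromosome II, 3 on chromosome III, 2 on chromosome IV, 2 on chromosome V and 1 on chromosome I.

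Several of these 15 regions were broad. The region at II 10541844 to 10557659 spanned 15816 bp, the widest peak of the combined list, with a combined q of 2.08e-43. Replicate 1 split it into 2 peaks and replicate 2 into 3 peaks. The region at V 6223040 to 6230245 was 7206 bp wide and was a single peak in each replicate, with q = 2.57e-18 in replicate 1 and 2.93e-26 in replicate 2. The region at I 7079171 to 7087961 was 8791 bp wide. Its combined q of 2.55e-47 stood against 5.1e-10 in replicate 1 and 1.42e-05 for the stronger of its 2 peaks in replicate 2. At X 8035912 to 8036951 a peak of 1040 bp had nearly equal values in the replicates, q = 6.97e-25 and q = 2.66e-25. At IV 8431268 to 8433409 a peak of 2142 bp had a combined q of 3.8e-36.

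The other regions of this set were narrower than 1000 bp. On chromosome III they were 7162158 to 7162754 (combined q = 1.82e-39) and 7854312 to 7854841 (combined q = 8.75e-36). On chromosome II they were 10174233 to 10174722 (combined q = 5.51e-36) and 10563134 to 10563784 (combined q = 3.24e-34). The latter began 5.47 kb beyond the 15816 bp region. The remaining 3 were V 18967611 to 18968000 (combined q = 1.01e-34), X 14525364 to 14526343 (combined q = 3.6e-34) and IV 654677 to 655465 (combined q = 5.26e-34).

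**Figure D1:**
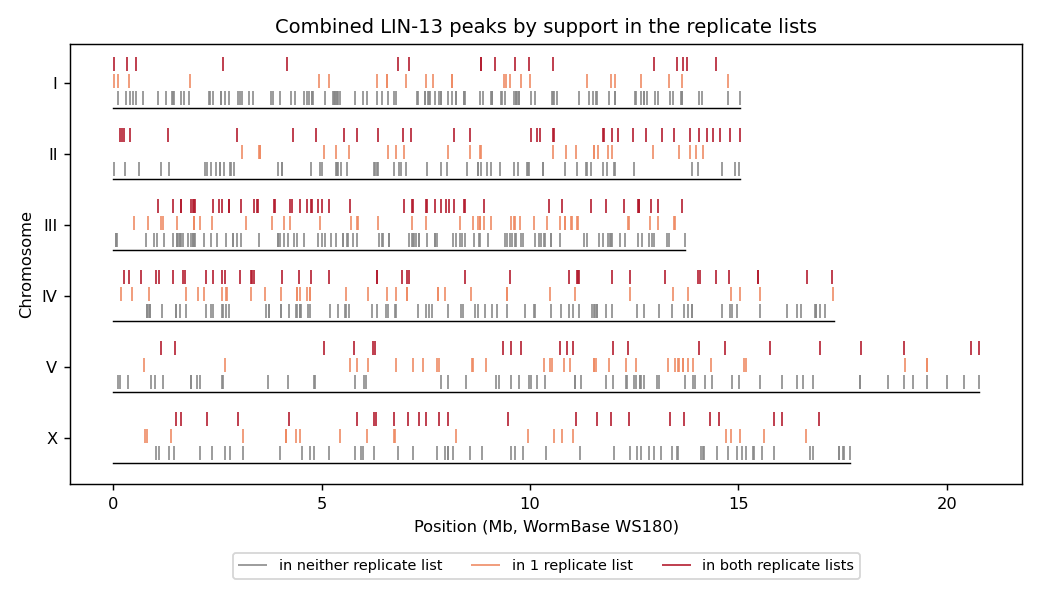
Positions of the 911 combined peaks along the 6 chromosomes (x axis, Mb in WormBase WS180; each tick is 1 peak midpoint, each black line runs to the last peak end). Red ticks are the 196 peaks that overlap a peak of both replicates, orange ticks those in 1 replicate list and grey ticks the 513 in neither. Chromosome III carries the most peaks in each of the 3 lists, and chromosome I is dominated by grey ticks.

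The replicates were compared to ask which regions were called in each of them. Of the 243 replicate 1 peaks, 198 overlapped a replicate 2 peak (81.5%, 95% interval 76.0 to 86.2). Of the 367 replicate 2 peaks, 199 overlapped a replicate 1 peak (54.2%, 95% interval 49.0 to 59.4). Random placement gave a mean of 1.51 overlaps in either direction and at most 10, so both counts were above chance (permutation of positions, p = 0.0001, one-sided, the smallest that 10000 placements can give). The midpoints of shared peaks lay a median of 30.3 bp apart, and 156 of 198 were within 100 bp. All of the 100 strongest replicate 1 peaks overlapped a replicate 2 peak, and 95 of the 100 strongest replicate 2 peaks overlapped a replicate 1 peak.

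Peaks found in a single replicate were weaker. In replicate 1 the median −log10 q was 7.54 for the 198 shared peaks and 5.01 for the 45 unshared ones, a difference of 2.53 (permutation p = 0.0003). In replicate 2 the medians were 8.74 for 199 shared and 5.23 for 168 unshared peaks, a difference of 3.51 (permutation p = 0.0001, the smallest possible). Where values of both lists rise together, a peak near the authors' limit in one list more easily misses it in the other. A difference in this direction therefore follows from the cut, and the p-values are not separate evidence of it. The strongest unshared peak of replicate 1 was V 2672248 to 2673012, with q = 6.73e-08 and rank 110 in its list. The strongest unshared peak of replicate 2 was a 3847 bp peak at I 7656539 to 7660385, with q = 1.76e-12 and rank 57. Both regions were also in the combined list, at q = 1.17e-09 and q = 4.68e-37.

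Regions strong in one replicate tended to be strong in the other. Over the 196 combined regions called in both replicates, −log10 q correlated with Spearman's rho = 0.66 (95% bootstrap interval 0.57 to 0.74) and Pearson's r = 0.86, each with permutation p = 1e-05, the smallest possible. These are correlations across regions within 1 pair of lists, and regions are not independent replicates. Only regions past the authors' limit in both lists enter, so weaker regions are not represented. The median −log10 q was 7.58 in replicate 1 and 8.79 in replicate 2, and the replicate 2 value was higher in 135 of the 196 regions.

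**Figure D2:**
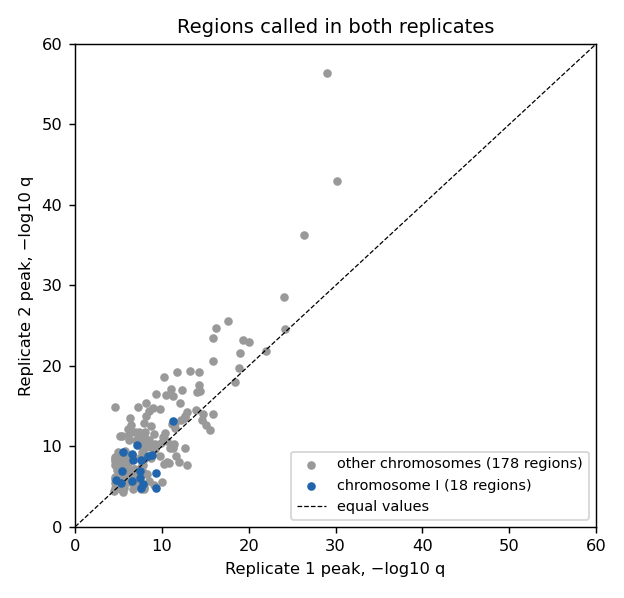
Authors' −log10 q in replicate 1 (x axis) and replicate 2 (y axis) for the 196 regions called in both; each point is 1 region, blue for the 18 on chromosome I and grey for the 178 elsewhere, and the dashed line marks equal values. The points rise together (Spearman's rho = 0.66), with 135 regions above the line.

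The combined list was then set against the replicate lists. It held 239 of the 243 replicate 1 peaks and 361 of the 367 replicate 2 peaks. Of its 911 peaks, 196 overlapped a peak of both replicates (21.5%, 95% interval 18.9 to 24.3), 42 a replicate 1 peak only, and 160 a replicate 2 peak only. The other 513 peaks (56.3%, 95% interval 53.0 to 59.6) overlapped no replicate peak. The count in both replicates is limited by the shorter list: 238 combined peaks overlapped the replicate 1 list and 356 the replicate 2 list.

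Combined peaks held by both replicates had lower q than those held by neither. The median −log10 q was 14.9 for combined peaks in both replicates and 5.34 for those in neither, a difference of 9.55 (permutation p = 1e-05, the smallest possible). Without the replicate 1 list, the difference between combined peaks in the replicate 2 list and those outside it was 5.33. How the combined list was made is not given in the sources used here. If it was called on the same ChIP libraries, a difference in this direction is built in, and the p-value is not independent evidence of it. In the strongest decile of the combined list, 84 of 92 peaks were in both replicates (91.3%, 95% interval 83.6 to 96.2) and 0 were in neither. In the second decile, 63 of 91 were in both (69.2%, 95% interval 58.7 to 78.5). In each of the 3 weakest deciles, 0 of 91 peaks were in both, with an upper 95% bound of 3.97%. Of the 196 peaks in both replicates, 99 were stronger than every peak found in neither. The strongest combined peak found in neither replicate, a region singled out after its value was seen, was I 12039410 to 12041330, with q = 2e-15 and rank 110.

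**Figure D3:**
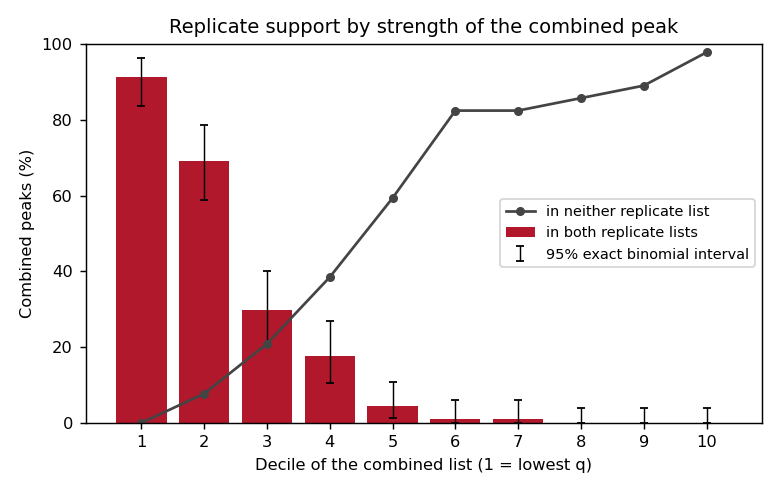
Share of combined peaks (y axis, percent) in each decile of the combined list ordered by q (x axis, 1 is the lowest q). Red bars are peaks in both replicate lists with exact binomial 95% intervals, and the dark line gives peaks in neither list; the bars go from 91.3% in the first decile to 0 in the last 3.

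Peaks lay on all 5 autosomes and on X, most densely on chromosome III. Among the 196 regions found in both replicates, chromosome III held 53, or 3.86 per Mb of the span reached by peaks (95% interval 2.89 to 5.05). Chromosome IV held 42 (2.43 per Mb, 1.75 to 3.29) and chromosome II held 35 (2.33 per Mb, 1.62 to 3.24). The X chromosome held 26 (1.47 per Mb, 0.96 to 2.15), chromosome V held 22 (1.06 per Mb, 0.66 to 1.60) and chromosome I held 18 (1.20 per Mb, 0.71 to 1.89). Chromosome III also had the highest density in the replicate 1 list, with 70 peaks (5.10 per Mb), in the replicate 2 list, with 90 peaks (6.56 per Mb), and in the combined list, with 213 peaks (15.5 per Mb). The X chromosome held 27 replicate 1 peaks (11.1%), 49 replicate 2 peaks (13.4%) and 110 combined peaks (12.1%, 95% interval 10.0 to 14.4). No test against chromosome length was made.

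The fullest 40 kb windows of the combined list, singled out after the lists had been seen, lay on chromosome III. The windows III 1900254 to 1940189 and III 1920862 to 1956900 overlapped and held 13 combined peaks each. Together they formed a run of 15 peaks over 56.6 kb, and outside this run no 40 kb window held more than 5. The strongest peak of this run was III 1938003 to 1938991, with a combined q of 4.57e-30. Replicate 1 had 5 peaks in the run, replicate 2 had 6, and 7 of the 15 combined peaks were in neither replicate list. Among 10000 random placements the fullest window held a median of 5 and at most 9 peaks (permutation of positions, p = 0.0001, the smallest possible).

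**Figure D4:**
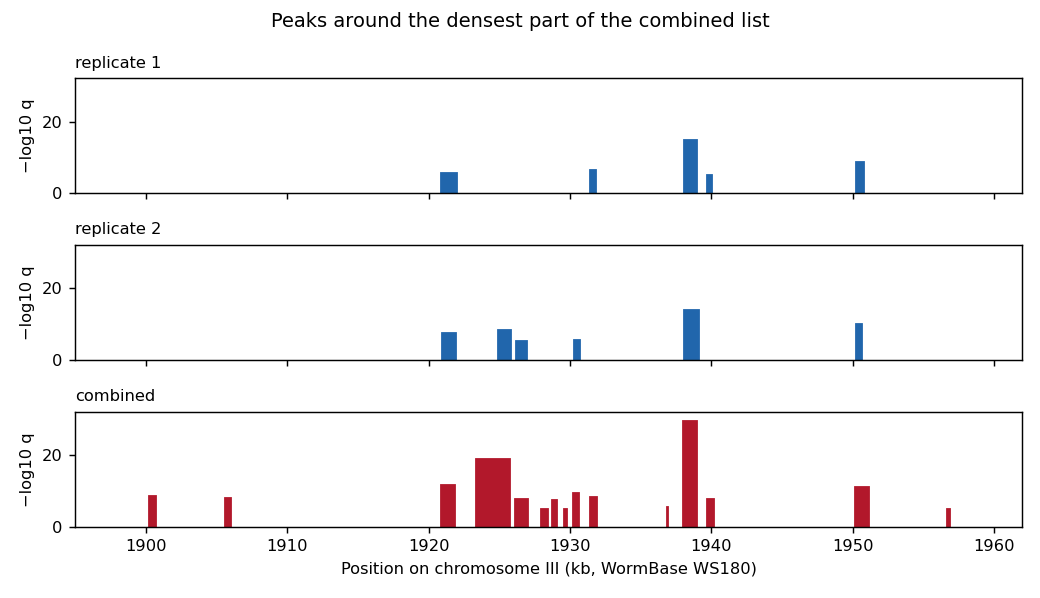
Peaks of replicate 1 and replicate 2 (blue) and of the combined list (red) around the run on chromosome III (x axis, kb in WormBase WS180; each box spans 1 peak, its height is the authors' −log10 q). The combined panel holds 15 peaks between 1900254 and 1956900, against 5 in replicate 1 and 6 in replicate 2.

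Chromosome I stood apart in the combined list. It held 24 of 243 replicate 1 peaks (9.88%) and 38 of 367 replicate 2 peaks (10.4%). In the combined list it held 162 of 911 peaks (17.8%, 95% interval 15.4 to 20.4). It held 118 of the 513 combined peaks found in neither replicate (95% interval 19.4% to 26.9%) but 44 of the 398 found in at least 1 (11.1%, 95% interval 8.15% to 14.6%), an odds ratio of 2.40 (95% interval 1.65 to 3.50; Fisher's exact test, adjusted p = 1.3e-05 over 6 chromosomes). The same comparison gave odds ratios between 0.80 and 0.96 on the other 5 chromosomes, none past the threshold (adjusted p from 0.46 to 0.92). This comparison was added after the lists had been seen.

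**Figure D5:**
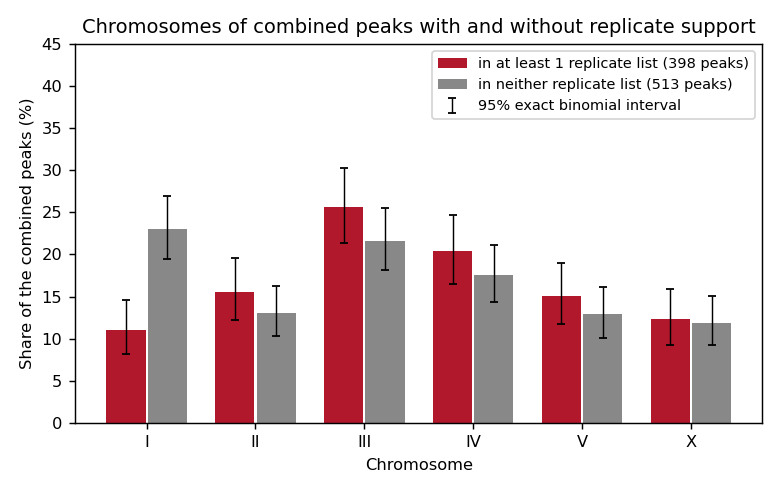
Share of combined peaks on each chromosome (y axis, percent; x axis, chromosome) for the 398 peaks found in at least 1 replicate list (red) and the 513 found in neither (grey), with exact binomial 95% intervals. The intervals of the 2 bars on chromosome I, for 44 and 118 peaks, do not overlap.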

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

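The choices were fixed before the data were examined, with exceptions. The circular shift of whole lists and the common q limit of 3e-05 (the highest q of replicate 1) were added after seeing the data. So were all tests of chromosome I, of the chromosome III run, of the parts of the autosomes and of peak width. Also outside the fixed plan were the comparison of shared with unshared peaks within each replicate list and the midpoint distances. The counts among the strongest peaks and the deciles were outside it too. Both replicate overlap shares stayed above chance under every alternative run (permutation of positions, p = 0.0001 each time): 74.1% to 86.1% of replicate 1 peaks and 49.0% to 57.1% of replicate 2 peaks were shared. The number of combined peaks found in both replicates was 196. It was 105 when only the stronger 50% of each list was used, a fall that follows from the shorter lists, and 165 to 196 under the other overlap rules, merging and the common q limit. Without replicate 2, 238 combined peaks overlapped the remaining list, and without replicate 1, 356 did. The common q limit left 344 replicate 2 peaks and 795 combined peaks, and a q limit 10 times lower left 163, 249 and 678 peaks in replicate 1, replicate 2 and the combined list. Merging peaks within 200 bp changed no count. Spearman's rho between the replicates ranged from 0.63 without the 10 strongest regions to 0.67 with a 50% reciprocal overlap, and Pearson's r from 0.77 on log2 values to 0.86. The difference in median −log10 q between supported and unsupported combined peaks ranged from 5.33 without replicate 1 to 7.75 without replicate 2, against 9.55 with both lists and 10.1 with a 50% reciprocal overlap. The chromosome I odds ratio ranged from 2.30 to 2.77, with Fisher's exact p at most 0.00024, including 2.41 without replicate 1 and 2.30 without replicate 2. The chromosome I difference in combined −log10 q minus the replicate sum was 2.79 within quintiles of that sum (permutation p = 0.0002), against 3.00 without matching. Of the 18 chromosome I regions, 9 were in quintile 3, 1 in quintile 4 and 0 in quintile 5, so the matching rests on few regions. The replicate values may themselves be lowered on this chromosome, so matching on their sum does not settle the cause. The X chromosome share of the lists and subsets ranged from 10.7% to 13.4%. Settings foreseen for gene starts, gene lists and an X share expected from gene numbers were not run, since no WS180 annotation was used. No paired analysis was possible because the input libraries, which share the numbers 1 and 2 with the ChIP libraries, have no peak list of their own among the data analysed. Depth is unknown, so a peak missing from a replicate list is a peak not called there, not a site shown to be unbound.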

Other observations

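The tests of the run of peaks on chromosome III and of the central parts of the autosomes, and the counts of narrow and wide peaks, were chosen only after the result was seen. The tests of chromosome I and of the combined value against peak width were written down before their results were computed, though the patterns themselves had been noticed in the data.

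The run of 15 combined peaks at III 1900254 to 1956900 is not accounted for by chance placement of peaks on the chromosomes, which gave at most 9 in a 40 kb window against 13 (permutation of positions, p = 0.0001, the smallest possible). A candidate explanation is 1 enriched domain that the peak caller cut at arbitrary positions. Of the 5 replicate 1 peaks in the run, 3 overlapped a replicate 2 peak, against a mean of 0.75 under placement within the run (permutation of positions, p = 0.024, one-sided). Within the windows of 13 peaks alone the counts were 2 of 4 (permutation p = 0.16) and 3 of 5 (permutation p = 0.076), so the outcome rests on where the run is taken to end, and with so few peaks a split domain and separate sites cannot be told apart. No biological explanation was tested, and a gain of copies in the strain would need the input reads, which were not used here.

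Chromosome I calls in the combined list were seldom found in a replicate, and 3 explanations were weighed. Neighbouring calls from a few split domains are argued against, since the odds ratio was 2.30 (Fisher's exact test, p = 4.3e-05) after peaks within 10 kb were joined. A different scaling of chromosome I between the combined and the replicate calling stays open and has a test in its favour: in regions found in both replicates, the combined −log10 q minus the sum of the replicate values had a median of 1.35 over 18 regions on chromosome I and of −1.65 over 178 regions elsewhere, a difference of 3.00 (95% bootstrap interval 0.53 to 4.88; permutation p = 0.0003). Within quintiles of combined q the odds ratio was 4.78 (permutation within quintiles, p = 0.0002). By the rule written beforehand, a value above 1 with p under 0.05 counted against weaker binding on chromosome I. The rule did not allow for combined q itself being raised on this chromosome. As it may be, matching on it decides nothing, and weaker binding also stays open. The chromosome I share was higher among peaks in neither replicate than among supported peaks in the 4 stronger quintiles. It was lower in the weakest (32 of 170 peaks against 3 of 12). Few supported peaks lay on chromosome I in some quintiles, 1 of 53 in quintile 3 and 1 of 29 in quintile 4. The lists alone do not say whether the combined values are raised or the replicate values lowered there. No biological explanation other than weaker binding was tested.

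The same excess of the combined value over the replicate sum was above 0 in 47 of 196 regions and above 5 in 6 of them, 3 on chromosome I and 3 on chromosome II. The excess was above 0 in 11 of 18 regions on chromosome I (61.1%) but in 7 of 35 on chromosome II (20.0%). Across the chromosomes other than I this share ran from 15.4% on X to 26.2% on chromosome IV. It was largest, 32.5, at I 7079171 to 7087961. Only the strongest peak of each replicate entered the sum, which enlarges the excess where a replicate holds several peaks. This region met 2 peaks in replicate 2. The stronger had a −log10 q of 4.85, so the weaker could add no more than that, and most of the excess there remains. The region at II 10174233 to 10174722 met 1 peak in each replicate and had an excess of 7.14, to which this rule does not apply. The region at II 10541844 to 10557659 (excess 11.8) met 2 peaks in replicate 1 and 3 in replicate 2. The hypothesis that a wider combined interval, holding more reads, gives the excess was tested over all 196 regions: the excess and the ratio of combined to replicate width had Spearman's rho = 0.025 (95% bootstrap interval −0.11 to 0.18; permutation p = 0.73), which neither shows such a relation nor excludes a weak one.

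The combined peaks were not concentrated toward the ends of the autosomes. The hypothesis that the outer parts hold more than their share was tested, with the span reached by peaks cut into 3 equal parts, on the 801 autosomal combined peaks: 299 (37.3%, 95% interval 34.0 to 40.8) had their midpoint in the central part (exact binomial test, p = 0.018), which is the opposite direction. As the hypothesis was written after this result was seen, the p-value is not an independent test of it. The central part held 71 of 162 peaks on chromosome I and 60 of 126 on chromosome V. Without chromosome I the share was 35.7% (exact binomial p = 0.21) and without chromosome V 35.4% (exact binomial p = 0.25), so the surplus in the middle rests on these chromosomes. Among peaks found in both replicates, 53 of 170 were in the central part (31.2%, 95% interval 24.3 to 38.7), an interval that leaves either direction open.

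In the combined list 14 peaks were narrower than 200 bp, down to 20 bp, a width that neither replicate list contained. Of these, 13 were in neither replicate and 7 were on chromosome III. Of the 24 combined peaks at least 3000 bp wide, 9 were in both replicates (37.5%), against 187 of 887 narrower ones (21.1%), which did not pass the threshold (Fisher's exact test, p = 0.074). The wide peaks were less often in neither replicate, 5 of 24 (20.8%) against 508 of 887 (57.3%; Fisher's exact test, p = 0.00053). They were also stronger, with a median −log10 q of 11.4 against 6.45, and the shares were not matched on strength.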
